A study of Homo sapiens with 12 samples.

How the data were processed

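Total RNA of T47D breast cancer cells was labelled with biotin and hybridised to Illumina BeadChip arrays, 12 in all, per the labels' protocols. The labels' treatment entry and title assigned each array to vehicle, R5020, telapristone (given there as CDB4124 or TPA) or both, with 3 replicates in each of the 4 groups and a treatment of 24 h. The labels disagree on the R5020 dose in the combination: the protocol text gives it in mM and each sample's own entry in nM; 10 nM, the entry of the sample, is used here, with 1 µM of telapristone.

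The deposited table of non-normalized values holds, per the file headers, the mean bead intensity of each probe on a linear scale and the probe's detection p-value on the same array. Neither background subtraction nor normalization is visible in the intensity values the authors deposited there, whose median was 100.73 to 105.37 per array. The detection p-value is deposited as the scanner software gave it, per the file headers. The series' value table also holds intensity values: on the linear scale they equal a quantile normalization of the deposited raw intensity values, with a largest relative deviation of 0.000391 and a median of 103.45 on each array, so its scale and centring are known, and it is not background corrected. The submitters' processing notes name lumi, with no version or step. What else was done upstream is not given in the sources used here. Columns of other samples in the tables numbered 0.

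The table has 47322 probes. After 93 control probes were left out, 47229 gene probes remained, of which 43959 had 1 gene symbol, 0 had several and 3270 had none. Symbols were updated to current ones through the Entrez gene number for 35671 probes and through the accession for 84, and 8204 kept the name in the file. The names of 54 probes had been turned into dates in the file, and all 54 were recovered through these identifiers. Chromosomes come from the RefSeq gene table. No coordinates are given, since the file names no genome build for its probe positions.

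Intensities were corrected, normalized and log2-transformed with neqc in limma 3.58.1 (R 4.3.3): normexp background correction with the background estimated from the detection p-values, an offset of 16, and quantile normalization. A probe was kept if its detection p-value was under 0.01 on at least 3 of the 12 arrays, which left 15756 gene probes, 15131 of them with a symbol. For each of the 12033 genes the kept probe with the highest mean over all arrays stood for the gene. Where a gene named here had other kept probes, none of them was called in the opposite direction. The detected share of probes, 28.48% to 31.83% per array, describes the signal over background, and the number of arrays limits the precision.

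One mean per group was fitted to all 12 arrays with lmFit, so that the groups shared one estimate of the spread (12.8 degrees of freedom after eBayes), and p-values were adjusted by Benjamini-Hochberg over all genes, with calls at 0.05. The comparisons were R5020, telapristone and the combination against vehicle, the combination against R5020 and against telapristone, telapristone against R5020, and the interaction. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists within a comparison, beside camera with an estimated correlation and fry; members were counted over all genes tested and adjusted over the list alone. Where all probes of a gene were not above background on the arrays of 1 group, the fold is given as "at least": the bright group's mean against the dim group's mean of, per array, the higher of the probe's own level and the lowest level among detected probes. No fold is given where both groups were below background. After results had been seen, the same bound was extended to genes named in the text whose chosen probe was detected on only some arrays of the dim group, such as OAS2 on 1 of the 3 R5020 arrays; counts and list medians were left as they were. List medians use the fitted differences. With such genes at their bound, or at 0 where no fold is given, the R5020 median of the receptor targets stayed at 1.55, and those of the interferon and G1/S lists became −0.40 and 0.01 from −0.41 and 0.05. Comparisons with a common group share its chance values; unchanged groups were simulated with 100 draws for the correlations and overlaps and 20 for the share of genes called the other way. The 3 arrays of a group could not be split so that each part kept 2.

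Genes named in the text followed a rule set before the data were examined, as were the gene lists, the design and the alternatives. In each comparison of 2 groups they are the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, up to 4 members with the smallest adjusted p of each list that passed or held at least 3 called members, and PGR, ESR1, MKI67 and CCND1 throughout. Genes named under the rule in one comparison are also quoted in others. ACTA2, CD68 and COL1A1 are all the called members of their list. MCM6 and MCM10 are named as called members of a gene set, the start of S phase, chosen after related results were seen.

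The procedure was tested on simulated arrays built from the measured vehicle levels and background, with the same spread, that of a typical gene, for all genes. For R5020 against vehicle, in 11995 genes, it recovered 24% of the genes changed 1.25-fold, 66% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, with 6 false calls among 148. For telapristone against vehicle, in 11993 genes, 16.3%, 81.6%, 98% and 98% were recovered, with 2 false calls. Estimated folds were shrunk: for R5020 against vehicle the median estimate of a 4-fold change was 3.52. In each of the 6 comparisons of 2 groups the changed list, of genes raised at least 1.5-fold, was called. The run was set to stop otherwise, so this outcome was required. Of 10 unchanged lists 0 were called. Simulated genes varied independently of each other, so this does not show how correlated genes affect the list tests.

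Alternatives covered the replicate number as a block, the detection filter, the background correction, the normalization (median scaling, cyclic loess), the series' value table, the mean of a gene's probes, a fit of only the groups compared, array weights, the variance prior, a fold of at least 1.5 and each array left out in turn. An alternative with the slide as a block was planned and not run, since the files used here give no slide or scan. No arrays were left out, and no pair of arrays had an equal raw signal at more than 1 probe. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.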

Results

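Gene expression was measured in T47D cells, an oestrogen receptor- and progesterone receptor-positive human breast cancer line, with Illumina BeadChip arrays, on which biotin-labelled RNA binds to gene-specific probes carried by beads. The cells were kept overnight in medium with hormone-stripped serum and then treated for 24 h. The 4 groups of 3 arrays each received vehicle, 10 nM of R5020 (promegestone, a synthetic progestin), 1 µM of telapristone (CDB4124, an antagonist of the progesterone receptor), or R5020 and telapristone together. Between 28.48% and 31.83% of the 47229 gene probes were detected on an array, and the median raw intensity lay between 100.73 and 105.37. Expression was tested for 12033 genes, and levels are given as log2 normalized intensity with the SD of 3 arrays. The labels number the replicates but do not say that they were separate cultures, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays, 3 per group, limits the precision of a level, and the median standard error of a log2 difference between groups was 0.112. The first principal component held 67.9% of the variance and placed the 3 R5020 arrays at 44.4 to 45, with the other 9 arrays at −17.3 to −11.2.

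The first comparison asked what the progestin alone did to these cells. R5020 raised S100P, which encodes a calcium-binding protein and lies on chromosome 4, from a level of 8.26 ± 0.01 to 13.88 ± 0.03 (SD, n = 3), a 49.0-fold increase. SLPI (chromosome 20), which encodes a secreted protease inhibitor, rose at least 38.4-fold, and SGK1 (chromosome 6), a serum- and glucocorticoid-regulated kinase, at least 19.3-fold; both were not above background in vehicle. NDRG1 (chromosome 8), a stress- and steroid-responsive gene, rose 5.45-fold. Among the genes that fell, the interferon-induced OAS2 (chromosome 12) dropped at least 11.6-fold and SRARP (chromosome 1), which encodes a steroid receptor-associated protein, 12.8-fold. The progesterone receptor gene PGR (chromosome 11) itself fell 4.95-fold, from 8.89 ± 0.05 to 6.59 ± 0.12 (limma adjusted p = 2.7e-10), and the oestrogen receptor gene ESR1 (chromosome 6) 1.83-fold.

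Of the 25 measured progestin- and glucocorticoid-receptor targets, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 difference of 1.55. They included HSD11B2, which inactivates cortisol and rose at least 18.4-fold, and the phosphatase gene DUSP1, which rose 5.47-fold. Other genes with large rises included TRNP1 at 27.0-fold, the acute-phase gene SERPINA3 at least 19.5-fold and the basal keratin gene KRT5 at least 10.1-fold. Besides OAS2 and SRARP, large falls included those of MKX (at least 6.8-fold), TCL1B (at least 6.25-fold), DLL1 (at least 5.13-fold), SEMA6A (at least 4.48-fold) and RIPOR3 (at least 3.94-fold).

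R5020 raised 61 of 63 measured genes of G2/M and mitosis and lowered none, with a median log2 difference of 1.14 and the same counts adjusted over the list alone. CDC20, the activator of the anaphase-promoting complex, rose 2.66-fold, PTTG1 (securin) 2.62-fold, the phosphatase gene CDC25C 2.76-fold and TACC3, which encodes a spindle protein, 2.34-fold. The proliferation marker MKI67 rose at least 1.8-fold and the cyclin D1 gene CCND1 1.97-fold. Among 17 cyclin-dependent kinase regulators 8 rose and none fell, also adjusted over the list alone. MYC rose 3.55-fold, and so did genes of cell cycle inhibitors, CDKN1A at 2.64-fold and CDKN1C at least 1.57-fold. Among 42 genes of the G1/S transition and DNA replication, by contrast, 7 rose and 8 fell over all genes and over the list alone, with a median of 0.05: TK1 (thymidine kinase) was 1.79-fold higher, whereas UNG, CCNE1 (cyclin E1) and CDT1 were lower by 1.69-, 1.51- and 1.45-fold. Of 22 DNA repair genes 6 rose and 4 fell, also over the list alone, MND1 being 1.96-fold higher and MSH6 2.17-fold lower. R5020 changed 39.3% of all genes tested, so a count of called members does not by itself set a list apart from other genes.

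Genes of fatty acid synthesis and targets of the aryl hydrocarbon receptor and NRF2 rose as groups. Of 24 genes of fatty acid synthesis and lipid droplets 14 rose and 3 fell, over all genes and over the list alone. THRSP, a regulator of lipogenesis, rose at least 7.56-fold, the fatty acid desaturase gene FADS1 5.04-fold, ACSL1 4.19-fold and ELOVL5 3.83-fold. Of 11 aryl hydrocarbon receptor and NRF2 targets 9 rose and none fell (10 and 1 adjusted over the list alone), among them TIPARP at 4.46-fold and the steroid-metabolising AKR1C2 and AKR1C3 at least 3.62- and 3.01-fold. Of 5 metallothionein genes, which encode metal-binding proteins, MT1X rose at least 3.34-fold, MT2A and MT1A rose 3.18- and 2.58-fold and MT1F fell 1.71-fold, with the same counts adjusted over the list alone. The list's call was lost at an adjusted p = 0.0807 with an estimated correlation.

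Of 31 interferon-stimulated genes 19 fell and 3 rose (20 and 4 adjusted over the list alone), with a median of −0.41. MX1 fell 2.68-fold, IFI35 2.32-fold and UBE2L6 1.84-fold; the list had an adjusted p = 0.0613 with an estimated correlation. Of 20 oestrogen-responsive genes 9 fell and 5 rose, adjusted over all genes and over the list alone, and the list did not pass with camera (adjusted p = 0.0524). MYB fell 4.62-fold and IGFBP4 2.77-fold, whereas GREB1 rose 2.07-fold. Among 21 luminal epithelial markers 8 rose and 10 fell (8 and 11 adjusted over the list alone), with GATA3, SPDEF and TFF3 lower by 1.93-, 1.83- and 2.11-fold. Among 13 basal and progenitor markers 5 rose and 4 fell (5 and 5 adjusted over the list alone), and KRT6A was at least 7.17-fold higher. Of 18 nuclear receptors and coregulators 7 fell and 2 rose, and of 20 growth factor, cytokine and Wnt genes 11 rose and 6 fell, each with the same counts over the list alone; STAT5A rose 8.47-fold, and TGFB3 and IGFBP5 fell 3.58- and 2.39-fold. Of the 4 non-epithelial markers measured 3 fell, over all genes and over the list alone: ACTA2, CD68 and COL1A1, by 0.38, 0.42 and at least 0.46 on the log2 scale. Among 15 reference genes 1 fell and none rose, also over the list alone, with a median of −0.02.

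R5020 changed 4731 of the 12033 genes (limma with Benjamini-Hochberg adjustment, threshold 0.05), of which 2043 were higher and 2688 lower. With cyclic loess normalization 2338 were higher and 2290 lower, so the excess of lower genes depends on the normalization. By camera, 7 of the 22 lists passed the test, and G2/M (adjusted p = 0.0128), receptor targets (0.000898), aryl hydrocarbon receptor and NRF2 targets (0.00469), fatty acid genes (0.00469) and kinase regulators (0.016) kept their call with an estimated correlation. Fry, which does not set a list against the other genes, called 10 lists that camera did not, among them the oestrogen-responsive genes (adjusted p = 7.44e-06), the luminal (1.51e-06), basal (1.78e-09) and non-epithelial markers (0.00155), the nuclear receptors (2.17e-06) and the growth factor genes (0.0499). For 390 of the called genes 1 group was not above background, so that their fold is a lower bound.

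**Figure D1:**
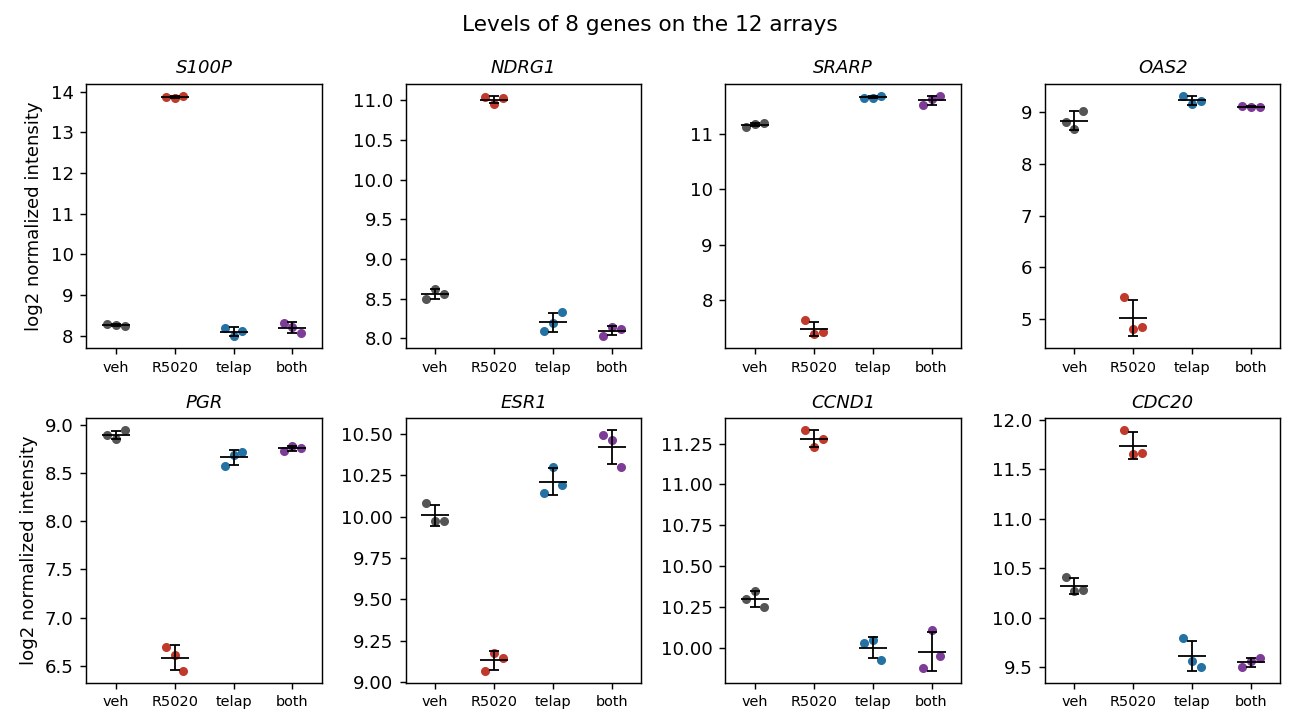
Log2 normalized intensity (vertical axes, not starting at 0) of 8 genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of a group (black bars). The groups are vehicle (veh), R5020, telapristone (telap) and R5020+telapristone (both). The R5020 arrays stand apart from the other groups for each of the 8 genes, as for S100P at 13.88 ± 0.03 against 8.26 ± 0.01 in vehicle.

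The second comparison asked what the antiprogestin did on its own. Telapristone lowered genes of cell division: 31 of the 63 G2/M and mitosis genes fell and none rose (56 and none adjusted over the list alone), with a median log2 difference of −0.54. KIFC1, a mitotic kinesin, was 1.74-fold lower at 7.63 ± 0.06 against 8.43 ± 0.09 (SD, n = 3), the kinase gene AURKB 1.73-fold, CDCA5 1.63-fold and CDC20 1.63-fold. ASPM, PBK and HMMR, which also serve mitosis, were lower by 1.86-, 1.78- and 1.76-fold. Of the 42 G1/S and DNA replication genes 9 fell and none rose (27 and none adjusted over the list alone), with a median of −0.36; E2F2, MCM2, POLE2 and GINS2 were lower by 1.53-, 1.49-, 1.45- and 1.45-fold. FANCD2 and FANCG were the 2 of 22 DNA repair genes that fell (9 adjusted over the list alone); that list had an adjusted p = 0.0934 with an estimated correlation. CDKN3, 1 of 17 kinase regulators (4 adjusted over the list alone), and the glycolytic gene PFKP, 1 of 24 genes of glycolysis and hypoxia (3 adjusted over the list alone), fell 1.44- and 1.39-fold.

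Outside the cell cycle, the largest fall was that of OLFML3, which encodes a secreted glycoprotein, from 10.10 ± 0.13 to 8.44 ± 0.14, or 3.15-fold (limma adjusted p = 1.1e-05). SCUBE2 fell at least 1.75-fold and the prolactin-induced PIP, a luminal marker, 1.74-fold. MT1F rose 1.91-fold, C1orf116 1.80-fold, the protease gene TMPRSS2 1.56-fold, KLF9, a steroid-responsive transcription factor gene, 1.45-fold, and SRARP 1.41-fold. KLF9 was the 1 of 25 progestin- and glucocorticoid-receptor targets that passed the test, also over the list alone, where 1 other fell; the list's median was −0.02. PGR had a log2 difference of −0.23 (adjusted p = 0.317), ESR1 of 0.20 (0.404) and CCND1 of −0.29 (0.142), and none of these passed the limma test. MKI67 did not pass either (adjusted p = 0.262); it was above background on 1 of 3 vehicle arrays and on none with telapristone, so no difference is given.

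Telapristone changed 124 genes, 17 higher and 107 lower, and 1 of them by 2-fold or more. The G2/M, G1/S, kinase regulator and glycolysis lists kept their call with an estimated correlation, at adjusted p = 0.00306, 0.00167, 0.047 and 0.047. The count fell whenever 1 array of either group was left out, which also leaves fewer arrays in that group. It was 19, 8 and 24 without vehicle replicate 1, 2 and 3, and 21, 90 and 24 without telapristone replicate 1, 2 and 3. With median scaling 67 genes were called, of which 32.8% were higher, against 13.7% of the 124.

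The third comparison asked what telapristone did to cells that also received R5020. Adding it lowered S100P 51.4-fold, SLPI at least 40.3-fold, SGK1 at least 20.3-fold and HSD11B2 at least 19.3-fold, and raised SRARP 17.3-fold and OAS2 at least 14-fold. PGR was 4.51-fold higher than with R5020 alone, at 8.76 ± 0.03 against 6.59 ± 0.12 (SD, n = 3), and ESR1 2.43-fold. CCND1 was 2.45-fold and MKI67 at least 1.87-fold lower. FBP1, which encodes an enzyme of gluconeogenesis, and NCAM2 were also among the largest rises, at 5.15- and 5.46-fold.

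Of the 63 G2/M genes 61 fell and none rose (62 and none adjusted over the list alone), with a median of −1.53: CDC20 fell 4.53-fold, TACC3 4.27-fold, BIRC5 (survivin) 4.05-fold and PTTG1 3.91-fold. Of the 42 G1/S genes 21 fell and 1 rose (22 and 1 adjusted over the list alone), TK1 by 2.54-fold and TYMS by 2.16-fold; the list's call was lost at an adjusted p = 0.0573 with an estimated correlation. Among the 25 receptor targets 19 fell and 1 rose, among 24 fatty acid genes 13 fell and 3 rose, each also over the list alone, and among 11 aryl hydrocarbon receptor and NRF2 targets 8 fell and 1 rose (9 and 1 adjusted over the list alone). FADS1 was 6.79-fold and NDRG1 7.50-fold lower. Of 17 kinase regulators 12 fell and none rose (12 and 1 adjusted over the list alone), with MYC 3.41-fold, CDKN2D 2.94-fold and CDKN1A 2.80-fold lower. Of 31 interferon-stimulated genes 19 rose and 4 fell (20 and 4 adjusted over the list alone), MX1 by 2.00-fold, and of 20 oestrogen-responsive genes 9 rose and 2 fell (10 and 3 adjusted over the list alone), MYB by 3.23-fold and IGFBP4 by 2.87-fold. These lists had adjusted p = 0.116 and 0.343 with an estimated correlation. So had the basal markers, of which 7 of 13 fell and 2 rose (adjusted p = 0.089), the metallothioneins, of which 3 of 5 fell and MT1F rose (0.116), each with the same counts over the list alone, and DNA repair, of which 11 of 22 fell and 3 rose, also over the list alone (0.427).

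Adding telapristone to R5020 changed 5135 genes, 2857 higher and 2278 lower; with cyclic loess the split turned to 2451 higher and 2579 lower. Of the 4731 genes changed by R5020, 3747 (79.2%) changed the other way: 1699 of the 2043 that had risen fell, and 2048 of the 2688 that had fallen rose. Of the 680 genes that R5020 changed at least 2-fold, all 680 changed the other way, including each gene with the largest rise or fall named above. Both comparisons use the R5020 arrays. In 20 simulations without a telapristone effect 0% of the genes were called the other way. This was nearly fixed in advance, since without such an effect hardly any gene can be called for the combination against R5020. It therefore does not measure how the shared arrays affect the 79.2%. Across genes, which are not independent replicates, the log2 differences of both comparisons had r = −0.93 (−0.5 with no effect) and a covariance of −0.2793 (−0.008 with no effect). Independent lists would share 387 and 638 genes in the opposite directions.

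**Figure D2:**
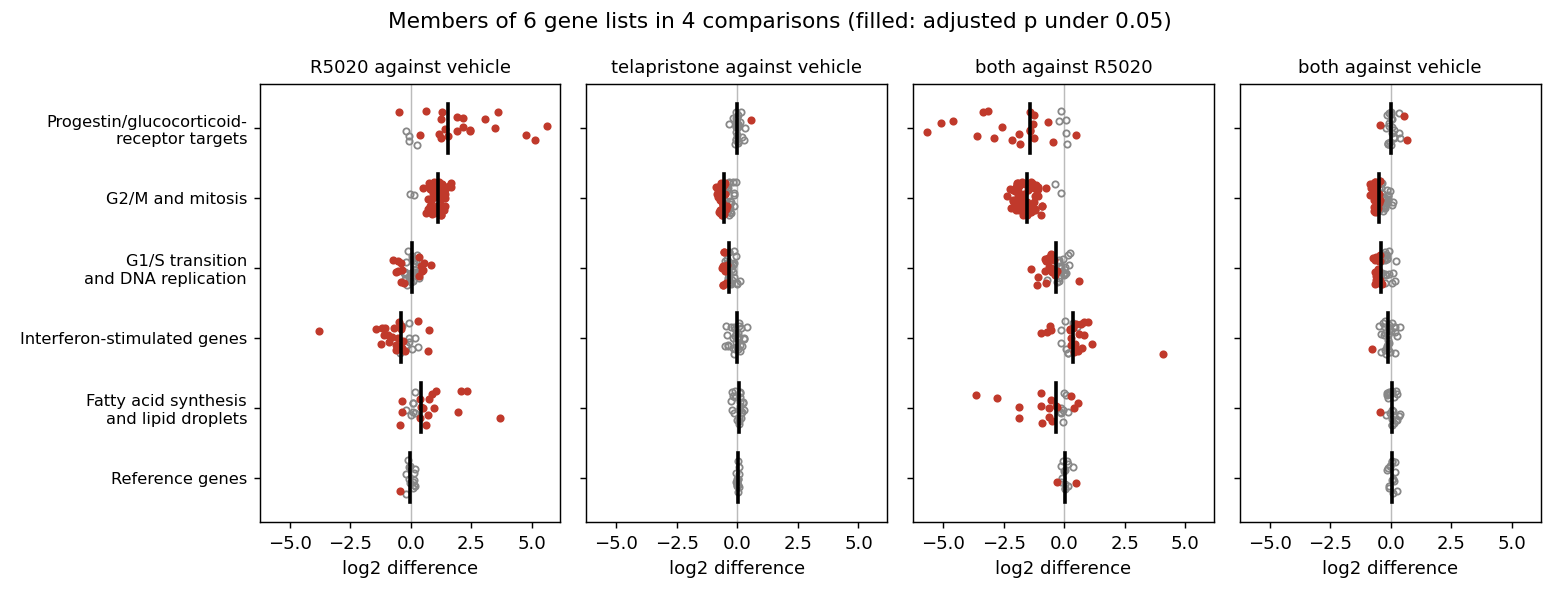
Log2 difference (horizontal axes) of each measured member of 6 gene lists in 4 comparisons, where "both" stands for R5020+telapristone; filled points have a limma adjusted p under 0.05, open points do not, and black bars are list medians. The G2/M genes had medians of 1.14 with R5020, −0.54 with telapristone, −1.53 for both against R5020 and −0.49 for both against vehicle, while the reference genes had medians of −0.02 to 0.04.

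The combination was then set against vehicle, which shows what differed from untreated cells when both ligands were present. Genes of cell division were lower here too: 29 of 63 G2/M genes fell (45 adjusted over the list alone) with a median of −0.49, and 18 of 42 G1/S genes (26 adjusted over the list alone) with a median of −0.38, and none rose in either list or count. TACC3 was 1.83-fold, AURKB 1.80-fold, KIFC1 1.78-fold, CDC20 1.70-fold and BIRC5 1.69-fold lower, and among replication genes MCM2 was 1.65-fold, E2F2 1.59-fold, CDC45 1.56-fold and MCM7 1.45-fold lower. The largest falls were those of OLFML3 at 2.77-fold, from 10.10 ± 0.13 to 8.63 ± 0.15 (SD, n = 3), PSRC1 at 1.91-fold and the histone gene H4C3 at 1.89-fold. C1orf116 was 2.00-fold, MT1F 1.76-fold and KLF9 1.60-fold higher. ESR1 was 1.33-fold higher (limma adjusted p = 0.023), while PGR, at a log2 difference of −0.13 (adjusted p = 0.412), CCND1, at −0.31 (0.0641), and MKI67 (0.641), close to background in both groups, did not pass the test.

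Of 22 DNA repair genes 4 fell (7 adjusted over the list alone), among them FANCD2 and RAD54L, with an adjusted p = 0.323 with an estimated correlation. PFKP was 1 of 2 glycolysis and hypoxia genes that fell, with NDRG1 (over the list alone 4 fell and 1 rose), and ISG15 the 1 interferon-stimulated gene (2 adjusted over the list alone). No kinase regulator passed over all genes (6 fell adjusted over the list alone), and none of the 4 non-epithelial markers did (2 fell adjusted over the list alone). With an estimated correlation these lists had adjusted p = 0.127 for glycolysis and for the kinase regulators, 0.277 for the interferon-stimulated genes and 0.259 for the non-epithelial markers, while G2/M and G1/S kept their call (0.0281 and 0.00923). The progestin- and glucocorticoid-receptor targets did not pass as a list (camera adjusted p = 0.459). KLF9 and WNT4 rose and NDRG1 fell, the same 2 and 1 as counts over the list alone. WNT4 was above background on 2 combination arrays and on 0 vehicle arrays, so no fold is given.

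In all, 309 genes differed between the combination and vehicle, 88 higher and 221 lower. Of the 124 genes changed by telapristone alone, 96 were also changed by the combination, 9 higher in both and 87 lower in both, where independent lists would share 0.124 and 1.97. The vehicle arrays are common to both comparisons, and part of this excess may come from them: the correlation across genes was 0.668 (0.5 with no effect) and the covariance 0.023 (0.008 with no effect). The count was 62, 93 and 161 without vehicle replicate 1, 2 and 3, and 150 and 90 without combination replicate 1 and 2.

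R5020 was next compared in the presence of telapristone, the combination against telapristone alone. No gene passed the test. S100P and NDRG1, which R5020 alone had raised, differed by log2 values of 0.10 and −0.11, and OAS2 and SRARP by −0.12 and −0.05. The 95% confidence interval of the difference was −0.08 to 0.28 for PGR and −0.09 to 0.37 for KLF9. ESR1 differed by 0.21 (adjusted p = 0.56) and CCND1 by −0.02 (0.954); MKI67, which was not above background with telapristone, did not pass (0.606). None of the 22 lists passed with camera, the smallest adjusted p (0.0546) being that of the 4 non-epithelial markers with a median of −0.22; G2/M and receptor targets had medians of 0.07 and 0.03. With limma 0 genes were called, the smallest adjusted p was 0.193, and 1018 genes had an unadjusted p under 0.05. The groups did not overlap for 14.2% of the genes, where chance gives 10%. In simulated data for this comparison 82% of 50 genes changed 1.5-fold were recovered, and 12.2% of 49 genes changed 1.25-fold, so small differences were not detectable. The simulation gave all genes the same spread and also changed genes 2- and 4-fold, which eases the adjusted threshold. Recovery may be lower where few genes change.

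**Figure D3:**
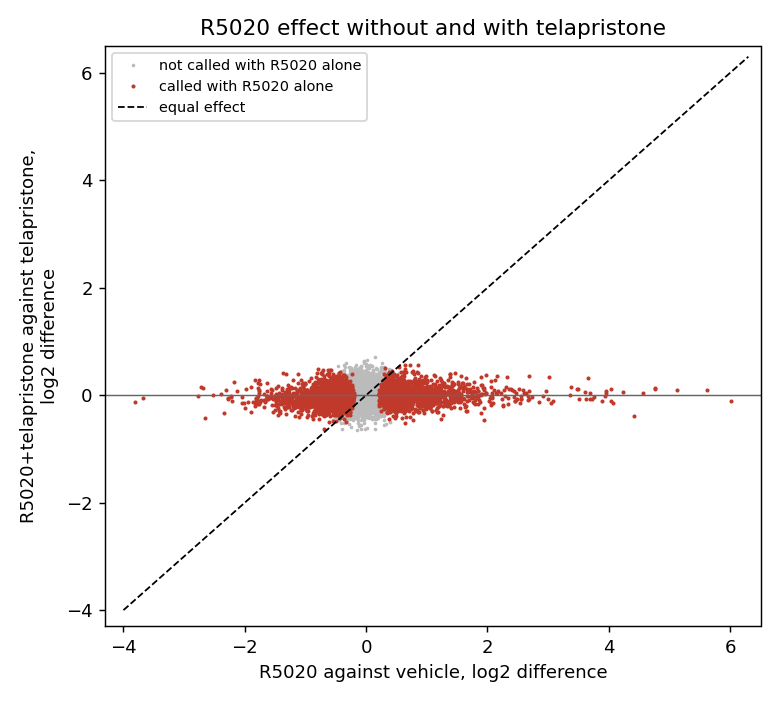
Log2 difference of R5020 against vehicle (horizontal axis) and of R5020+telapristone against telapristone (vertical axis) for each of the 12033 genes; red points were called with R5020 alone, the dashed line marks equal effects and the horizontal line a difference of 0. The vertical values stay near 0 over the whole range of R5020 effects, which reaches a fitted 6.01 for SLPI on the horizontal axis (at least 5.26 as a bound, since it was not above background in vehicle) and 0.71 at most on the vertical axis.

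The 2 ligands can be set side by side, although their doses differ (1 µM of telapristone, 10 nM of R5020). Both are synthetic steroids, and telapristone carries a dimethylaminophenyl group on the steroid ring system that R5020 lacks. With telapristone S100P was 8.10 against 13.88 with R5020, a log2 difference of −5.78, and TRNP1 differed by −4.77, whereas OAS2 was at least 15.2-fold and SRARP 18.0-fold higher with telapristone. PGR was 4.22-fold higher with telapristone (95% confidence interval of the log2 difference 1.89 to 2.26) and ESR1 2.11-fold. KLF9, raised by each ligand, was lower with telapristone by a log2 difference of −1.39 (95% interval −1.61 to −1.16). For C1orf116, also raised by each, the difference was 0.07 with a 95% interval of −0.18 to 0.32, which does not show that the ligands acted alike.

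Of 63 G2/M genes 62 were lower with telapristone than with R5020 and none higher, over all genes and over the list alone, with a median of −1.59. Of 25 receptor targets 19 were lower and 1 higher, and of 24 fatty acid genes 13 were lower and 3 higher, each also over the list alone. Of 42 G1/S genes 20 were lower and 1 higher, again over the list alone too (adjusted p = 0.0531 with an estimated correlation), and of 31 interferon-stimulated genes 20 were higher and 4 lower, over the list alone as well (0.0982). In all 4982 genes differed, 57% of them higher with telapristone. With median scaling the median log2 difference of all genes was 0.142 in this comparison, against 0.058 with quantile normalization, and 5407 genes were called, of which 69.2% were higher, while cyclic loess gave 4853 genes, of which 49% were higher, so the direction of the split depends on the normalization. Between the effects of the ligands against vehicle, 99 genes were called in both: 70 rose with R5020 and fell with telapristone (18.2 for independent lists), 18 fell with both (23.9), 6 rose with both (2.89) and 5 fell with R5020 and rose with telapristone (3.8). Both comparisons share the vehicle arrays, and across genes the correlation was −0.022 (0.499 with no effect) and the covariance −0.0019 (0.008 with no effect).

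The interaction tested directly whether the R5020 effect differed with and without telapristone. It did for 2987 genes, among them S100P (log2 difference of the effects −5.52), NDRG1 (−2.55), PGR (2.40), ESR1 (1.08) and CCND1 (−1, adjusted p = 3.74e-05). Of 63 G2/M genes 54 had a negative interaction and none a positive one (58 and none adjusted over the list alone), and of 25 receptor targets 19 had a negative and 1 a positive one, also over the list alone. MKI67 did not pass (adjusted p = 0.0844). Of 31 interferon-stimulated genes 13 had a positive interaction and none a negative one (16 and 2 adjusted over the list alone; adjusted p = 0.0787 with an estimated correlation). Of 42 G1/S genes 4 had a positive and 3 a negative interaction (2 and 2 adjusted over the list alone), and this list did not pass (camera adjusted p = 0.713).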

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

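The splits of the arrays and the slopes below were set out before their results were seen.

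The R5020 effect differed with and without telapristone for 2987 of 12033 genes by the interaction term, a difference between groups under the same treatment. Of 100 assignments of the 12 arrays to 4 groups, the real one and 99 random ones, 2 gave as many genes, a share under the 5% set beforehand. The highest other count, 3176, came from a random assignment that kept the 3 R5020 arrays together, as 2 of the 99 did; those that parted them gave at most 0. The count therefore follows the R5020 arrays as a set, which is the structure of the samples that the first principal component shows. The test registers only that the R5020 arrays stand apart. It cannot exclude a chance assignment of the other arrays as a source of the count.

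No gene was called when R5020 was added to telapristone, and the weighing of this pattern concerns what could hide an R5020 effect. Too little precision to see an effect of equal size is argued against by a slope over the 4731 genes called with R5020 alone. It is the slope of the effect with telapristone on the effect without. Across the 9 pairs of a combination and a telapristone array it was at most 0.053, where an effect of equal size would give a slope near 1 in each pair. It does not address precision for small changes of single genes, since simulated data gave 12.2% recovery of genes changed 1.25-fold. A small remainder of the R5020 effect stays open. The slope in the fit was 0.023, 8 of the 9 pairs lay above 0, and 2 of the 20 ordered splits of these 6 arrays gave a slope as high (exact one-sided permutation p = 0.1, with the highest other split at 0.025). Of the 680 genes changed at least 2-fold by R5020, 61% moved in the R5020 direction, with a median of 0.036 on the log2 scale.

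For the comparisons of 2 groups, 10 splits of 6 arrays are too few for a share under 0.05. In R5020 against vehicle, telapristone against vehicle, the combination against R5020 and against vehicle, and telapristone against R5020, the real counts were 4731, 124, 5135, 309 and 4982; in each 1 of the 10 splits gave as many genes, the real one, and the highest other count was 0. For the combination against telapristone 10 of 10 splits gave as many, since the real count and the highest other count were both 0.

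Probes without a gene name stood outside the gene comparisons, and 115 of the 625 that were kept by the filter were called in R5020 against vehicle, 36 higher and 79 lower. With telapristone against vehicle 2 of them were called, and with the combination against telapristone 0 by limma.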

How the results depend on the processing

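No named gene or list that was called reversed under any alternative in which it could be computed, but the split between directions did. Of the calls, 43.2% were higher with R5020, 55.6% for the combination against R5020, 57% for telapristone against R5020 and 52.6% in the interaction; with cyclic loess these became 50.5%, 48.7%, 49% and 46%, and with median scaling 46.9% in the interaction, so no majority of either direction is claimed for these. Calls of named genes were lost, mostly against vehicle with telapristone present: leaving out 1 array lost 174 calls over 4080 values, 106 of them for telapristone and 63 for the combination against vehicle. The 4080 values, and the 340 of each other setting, include values that had no call to lose. The 4080 also include arrays outside the comparison, so neither number is a base for a rate of loss. Of 340 values, 32 were lost at a fold of 1.5, 20 with only the 2 groups compared, 15 without a filter, 6 each with median scaling and the replicate block, 5 each without background correction, with normexp at the offset of 50 and with the value table, 4 with the trend and 1 with cyclic loess. Detection on all 12 arrays left 264 values, and none of their calls was lost. A fold of at least 1.5 left 1913 genes with R5020, 55 with telapristone, 2198 for the combination against R5020, 102 for it against vehicle, 2088 between the ligands and 1962 in the interaction, and by its construction it can only remove genes. The counts against vehicle with telapristone present moved most, and the cause was not tested except where genes or arrays were fewer. Telapristone called 124 genes and the combination 309; without a detection filter these became 62 and 180 (30470 genes tested), without background correction 209 and 590, with normexp at an offset of 50 they became 191 and 533, with the values of the series' own table they became 209 and 590, with only the 2 groups compared 47 and 128, with array weights 206 and 626, and with an intensity trend and robust prior 189 and 523. Median scaling gave 67 for telapristone. No background correction and the value table are the same values, since the table is a quantile normalization of raw signals, and each called 1 gene for the combination against telapristone. Of the 124 telapristone genes 111 were also called without background correction and 62 with median scaling. The split of the 309 calls changed from 28.5% higher to 42% without background correction and 41.9% with the trend.

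The share of R5020 genes called the other way, 79.2%, was 77.7% without a filter, 74% with only the 2 groups compared, 77.9% with array weights and 81.3% at a fold of 1.5. Leaving out 1 array at a time gave 3985 to 4843 genes with R5020, 8 (without vehicle replicate 2) to 123 with telapristone, 4453 to 5084 for the combination against R5020, 62 (without vehicle replicate 1) to 330 for it against vehicle, 0 for it against telapristone, 4247 to 5049 between the ligands, 2539 to 3057 in the interaction and a share of 73.4% to 83.2%. Telapristone also fell to 19 and 24 without vehicle replicate 1 and 3 and to 21 and 24 without telapristone replicate 1 and 3, and the combination to 93 and 161 without vehicle replicate 2 and 3 and to 150 and 90 without combination replicate 1 and 2.

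With an estimated correlation 23 of 154 list tests lost their call; with fry 37 gained one and 1 lost it. Leaving out 1 array lost 16 list calls over 1848 tests, 13 of them for the combination against vehicle, and gained 7. These numbers of tests include lists that had no call to lose. Detection on all 12 arrays lost 7, median scaling and no filter 3 each, and the other settings run for lists 1 each. For the combination against telapristone, cyclic loess and the mean of a gene's probes each gained 2 list calls and leaving out 1 array gained 5, so the absence of list calls there depends on the setting. The replicate numbers gave no clear pairing of the arrays, though a weak one is not excluded. Of 18 same-number pairs 4 had deviations from their group means correlated above 0.1, over a range of −0.22 to 0.21. The median correlation was 0.035 for the same number and −0.008 for different numbers, and 6 of 12 arrays correlated best with their own number. With the replicate number as a block the counts were 4744, 89, 5137, 296, 0, 4998 and 3001 in the order R5020, telapristone, combination against R5020, against vehicle and against telapristone, ligands, and interaction, and the share was 79.3%. The slide as a block was not run, since the files used here name no slide. Signal over background limits the folds of dim genes, as for the 390 genes called with R5020 that have only a bound.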

Other observations

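Tests of the start of S phase, dim probes, cycling share and progestin signalling in vehicle were all set out after related results were seen. Those of scaling and of single arrays were set out before their own values were seen, for a pattern that had already been found. The rules for the start of S phase, for dim probes and for progestin signalling were also changed after their own values were seen, as said at each.

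Several gene groups had members called in both directions with R5020 and did not pass with camera, while fry called glycolysis and hypoxia (adjusted p = 0.000299), the immediate-early genes (3.48e-05), the unfolded protein response (0.000463) and the p53 targets (0.00177). Over all genes 39.3% were called with R5020, and fry does not set a list against the other genes. Its calls therefore do not show that these groups moved more than other genes. Of 24 glycolysis and hypoxia genes 10 rose and 6 fell (10 and 8 adjusted over the list alone): the glycolytic ALDOA rose 1.86-fold and BNIP3 1.73-fold, whereas ADM, which encodes the vasodilator adrenomedullin, fell 3.40-fold. Of 19 immediate-early and MAPK feedback genes 6 rose and 6 fell (6 and 7 adjusted over the list alone), the phosphatase gene DUSP1 rising 5.47-fold, JUNB 2.08-fold, and the feedback inhibitor gene SPRY2 falling at least 2.7-fold. Of 21 adhesion, cytoskeleton and migration genes 6 rose and 9 fell (6 and 10 adjusted over the list alone), CALD1 rising 3.89-fold and TIMP1 falling 1.90-fold. Of 23 cholesterol genes 4 rose and 5 fell (5 and 6 adjusted over the list alone), DHCR7 rising 1.39-fold and SC5D falling 1.75-fold. Of 24 unfolded protein response genes 6 rose and 2 fell (5 and 2 adjusted over the list alone), and of 20 p53 targets 4 rose and 2 fell, also over the list alone, with BTG2 1.61-fold higher and XPC 1.54-fold lower.

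KLF9 and C1orf116 rose with each ligand against vehicle. Of the 99 genes called with each ligand, 6 rose and 18 fell with both, while 70 and 5 moved in opposite directions. KLF9 rose by 1.92 on the log2 scale with R5020, 0.54 with telapristone and 0.68 with the combination, and C1orf116 by 0.78, 0.85 and 1.00. Other genes were moved in opposite directions: MT1F and TMPRSS2 fell with R5020, by 0.77 and 0.73, and were raised by telapristone alone (0.93 and 0.64) and by the combination (0.82 and 0.72), and OLFML3 rose by 0.82 with R5020 and had differences of −1.65 and −1.47 with telapristone and the combination against vehicle.

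G2/M genes were lower with telapristone than with vehicle although no progestin had been added. Scaling of the arrays is argued against, since the G2/M median lay 0.56 below that of all genes under cyclic loess. Median scaling also gave −0.56, but it shifts all genes of an array alike and could not have changed this difference. A single deciding array is argued against too, since the G2/M median was −0.5 or lower without each of the 6 arrays. A candidate explanation is progestin signalling left in the vehicle cells and blocked by telapristone. It stays open, on a test whose rule was changed after its value was seen. As first run, over 351 genes raised at least 2-fold by R5020 at any vehicle level, the median difference with telapristone was −0.03, 57.5% were below 0, and the explanation was rejected. Genes at the floor in vehicle cannot fall, so a vehicle level was then asked for: the 142 genes raised at least 2-fold by R5020, outside the cell cycle lists and at a vehicle level of 7 or more, had a median difference of −0.06, 68.3% were below 0, and the outcome became undecided. The choice of these genes and their difference both use the vehicle arrays, which alone gives a positive correlation (0.499 with no effect). The difference may thus be shifted upward, and it was not corrected for this. Movement in the same proportion as the G2/M genes would have given −0.64, beyond the lower quartile of the 142 genes, −0.26. The values thus do not show that proportion, which the explanation does not require.

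With R5020 the G2/M genes rose by a median of 1.14 and the G1/S genes by 0.05. Dim probes that hide G1/S changes are argued against, because with telapristone against vehicle the G1/S median was 0.66 of the G2/M median, a test that replaced an undecided one, in which the vehicle levels of the lists differed by −0.11. A larger share of cycling cells and nothing else would raise both lists, and the G1/S genes did not rise as a group (upper quartile 0.24). The ratio of the medians, 0.04, is computed from the values that define the pattern. It restates the pattern and is no separate test of this explanation. Cells past the start of S phase when collected remain a possible explanation that the values do not decide: 15 genes of that step had a median of −0.19 with quartiles of −0.31 and 0.09, 4 of them (CCNE1, CDT1, MCM6 and MCM10) were called lower and 1 (CDC45) higher. By the first rule, a median below 0, this explanation had passed; after the value was seen the upper quartile was asked to be below 0 as well. The design holds 1 time point, so the order of events was not tested.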
